A study of Mus musculus with 9 samples.

How the data were processed

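Sciatic nerves of C57BL/6 mice were collected from control littermates, from PINCH1 mutants and from PINCH2 mutants, and total RNA was sequenced from TruSeq libraries, per the labels. Each of the 3 libraries of a group was a pool of 4 nerves, from 1 male and 1 female. The age was given as postnatal day 15 in 1 label field and as postnatal day 14 in the protocol. How the mutants were made is not given in the sources used here.

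Per the submitters' processing notes, reads were handled with Trim Galore 0.4.2, cutadapt 1.9.1 and HISAT2 2.0.5 on the mouse genome build GRCm38. The counting tool, its strand setting, the annotation release and the strandedness of the library kit are not given in the sources used here. The deposited table, made by the authors, held whole-number read counts for 25965 gene entries in each library, with no scaling for depth or gene length. No entry lacked a name, and all columns of per-sample values were used. Library totals ran from 957828 to 1204964 counts. A count of 0 allows up to 3 counts, which was 2.49 to 3.13 CPM (counts scaled to the library total) depending on the library. Such limits cover counting error only. They are too narrow here, because entries with a mean of 2 to 20 counts had a median variance of 2.09 to 2.29 times their mean within groups. Odd values also outnumbered even ones at low counts: 83.6% of the values from 1 to 4 were odd, against 50.1% of those over 50. What the odd values do to the limits was not tested.

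Entries were matched by gene identifier to the GENCODE M21 annotation of the same build, where 96.4% of them were found. With bedtools 2.31.1, the exons of each entry were compared with exons of genes on the opposite strand. An entry with such an overlap is said here to lie over that gene, its partner. Entries without a partner were searched for the nearest opposite-strand gene within 5000 bp. In all, 24.7% of the entries had a partner, and 89.7% of the counts fell on them. A count under a gene's name therefore could not be told from transcription of its partner, and the partner or neighbour is named beside the entries that passed or came next in order.

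Differential expression was tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F-test with robust dispersion, TMM scaling, the filterByExpr filter and all 9 libraries in 1 model with genotype as the only term. The filter kept 4738 entries, 2821 with a partner and 1917 without. P-values were adjusted by the Benjamini-Hochberg method over all tested entries, with a threshold of 0.05. Because the replicates were pools of nerves, p-values measure the spread between pools. Standard errors (SE) are the absolute log2 fold change divided by the square root of the F statistic. Means with SD are of TMM-scaled CPM over 3 libraries.

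A total of 37 gene lists were written before the data were examined. They were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists in each comparison. The named entries were also set by a rule made before the data were examined: Lims1 and Lims2; entries past the threshold with an official symbol, a mean of at least 1 CPM and no overlap between the groups, up to 10 in each direction; where fewer than 10 entries passed, the 10 with the smallest p that met the other criteria, named as not passing; and for lists, up to 4 members past the threshold or, where none passed, the 2 with the highest mean CPM. RP24-538B17.1, Afap1l1 and the partner entries fall outside that rule and were chosen after their values were seen.

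The edgeR procedure was tested on simulated counts for the comparison of PINCH1 mutants with controls, drawn for 4738 entries with 200 changed at random. Of the changed entries that were tested, 25.0% of 92 with a 2-fold change and 82.1% of 95 with a 4-fold change were recovered, and 9 of the 110 calls were on unchanged entries. In a second simulation for that comparison, on 4463 entries, a list of 20 entries lowered 1.5-fold was called and 0 of 20 unchanged lists were. Entries were drawn independently, so this could not check for false list calls that come from correlation between members. To set the correlation of the 2 mutants' changes against chance, all 9 libraries were drawn 100 times with unchanged groups. In each draw both mutants shared the same simulated controls, and entries were drawn independently.

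Alternatives set before the data were examined were RLE and upper-quartile scaling, TMM without the 20 most abundant entries, DESeq2 1.42.0, limma-voom, no filter, a filter of at least 1 CPM in at least 3 libraries, only the 6 libraries compared, the replicate number as a block, an adjusted p threshold of 0.01, a change of at least 1.5-fold, and each library left out in turn. For the lists, an estimated correlation and fry were also used. Scaling entries with and without a partner separately, a minimum of 3 members per list, and testing lists through the entries that lie over their members were added after the data were seen. No pair of libraries in a group agreed within sampling noise (chi-square per degree of freedom from 4.30 to 12.6), so each was counted as a separate replicate.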

Results

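The transcriptome of the sciatic nerve was compared between control mice, PINCH1 mutants and PINCH2 mutants at about 2 weeks of age, with 3 pooled libraries in each group. PINCH1 and PINCH2 are adaptor proteins made of LIM domains, encoded by Lims1 and Lims2, that join integrin-linked kinase (Ilk) and parvins at integrin adhesions. The sciatic nerve holds axons, the Schwann cells that ensheathe and myelinate them, fibroblasts, vessels and immune cells. Totals per library ran from 957828 to 1204964 counts, and 9674 to 11240 of the 25965 gene entries had at least 1 count in a library.

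The entries with the highest counts were mostly those that lie over another gene on the opposite strand. Of the 100 entries with the most counts, 93 had such a partner, against 24.7% of all entries. Taf10, a subunit of a general transcription factor, had 10421 to 10909 counts in controls, while Ilk, which it overlaps, had 152 to 202. Syn3, a synapsin gene, had 26320 to 39160 counts in controls, and Timp3, a metalloproteinase inhibitor gene on the other strand, had 74 to 102. On the mitochondrial genome, mt-Nd6, which is encoded on the other strand from mt-Co1 and mt-Cytb, took 80.9% to 91.6% of the mitochondrial counts of each library. Myelin genes without a partner were still counted, and Mbp, within whose span Rpl21-ps8 lies on the other strand, had 2393 to 3645 counts in controls.

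The targeted genes were examined first. Lims1 (chromosome 10, positions 58323466 to 58424691, GRCm38) had 3, 7 and 7 counts in the controls, 0, 1 and 3 in the PINCH1 mutants and 0, 1 and 9 in the PINCH2 mutants. Lims2 (chromosome 18, 31931507 to 31958619) had 9, 1 and 5 counts in the controls, 5, 3 and 1 in the PINCH1 mutants and 5, 1 and 1 in the PINCH2 mutants. Both were removed by the filter on low counts. Without it, the log2 fold change of Lims1 in PINCH1 mutants was -2.00 (SE 1.29, edgeR adjusted p = 0.806), and that of Lims2 in PINCH2 mutants was -1.03 (SE 1.22, edgeR adjusted p = 0.905). At counts this low, neither entry could show a loss. Counts under these names may also come from the opposite strand, so the entries are not shown to measure Lims1 or Lims2. The entry that lies over Lims2 is Gpr17, a G protein-coupled receptor gene on the minus strand of chromosome 18 (31942997 to 31949636). Its exons overlap 2 Lims2 exons, at 31944139 to 31944205 and 31944436 to 31944556. Gpr17 had 321, 211 and 380 counts in the controls, 330, 244 and 425 in the PINCH1 mutants and 113, 151 and 67 in the PINCH2 mutants. No entry lay over Lims1 exons in the same way.

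The comparison of PINCH1 mutants with controls asks which entries differ in count when PINCH1 is mutated. Counts under an entry's name may come from the strand opposite to the named gene. They are not shown to measure that gene, with or without a partner. Zdhhc17, a palmitoyltransferase gene, was 5.21-fold higher in the mutants, at 397 ± 47.2 CPM (SD, n = 3) against 76.2 ± 6.82 in controls. Camk4, a calcium/calmodulin-dependent kinase gene that lies over 2310026I22Rik, was lower, at 30.01 ± 5.65 CPM against 95.2 ± 39.4. The clone-named entry RP24-538B17.1, which was named because so few entries passed, was also lower, at 10.5 ± 3.09 CPM against 46.0 ± 13.6. Myelin, lipid synthesis and actin lists lay below the other entries in the mutants, as a set test with a preset correlation called them, although 0 of their members passed singly and the calls were lost with an estimated correlation.

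These were 1 higher and 2 lower entries of the 4738 tested with edgeR, and 302 entries had an unadjusted p under 0.05, where 236.9 were due by chance. Zdhhc17 (chromosome 10, 110941782 to 111010066, minus strand) had a log2 fold change of 2.38 (SE 0.19, adjusted p = 1.07e-07). It ends 2160 bp from Csrp2, a LIM-domain protein gene on the plus strand. Camk4 (chromosome 18, 32939041 to 33195767) had a log2 fold change of -1.66 (SE 0.30) and RP24-538B17.1 (chromosome 10, 4391587 to 4396424; 3479 bp from Zbtb2) one of -2.13 (SE 0.39), both with an adjusted p of 0.032. The number of lower entries fell to 0 with limma-voom, with the 6 libraries alone, at an adjusted p of 0.01, and without control replicate 1 or any 1 of the PINCH1 mutant libraries. It was 1 without control replicate 3, without PINCH2 mutant replicate 3 and with the 2 classes of entries scaled separately, and without control replicate 2 there were 4 higher and 5 lower entries.

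**Figure D1:**
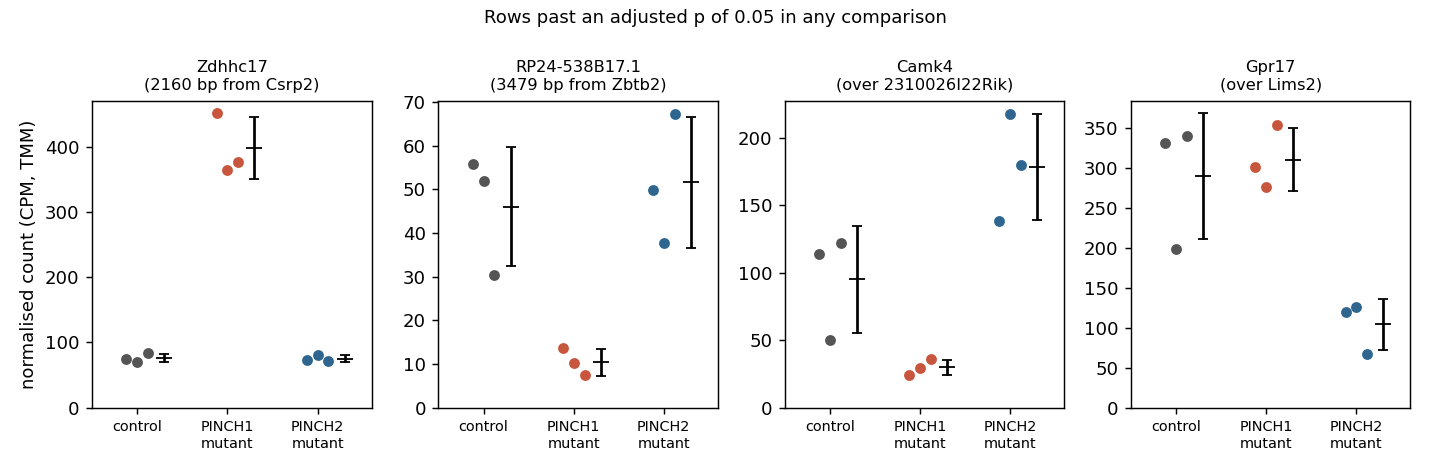
Normalised counts (CPM after TMM scaling, linear axes from 0) of the 4 entries that passed an adjusted p of 0.05 in any comparison, with 1 point per library and the mean ± SD of each group of 3. The panel titles name the opposite-strand gene over which each entry lies, or the nearest one. Zdhhc17 averaged 397 CPM in PINCH1 mutants against 76.2 in controls, and Gpr17 averaged 104 CPM in PINCH2 mutants against 290.4 in controls.

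A further 10 entries had the smallest p among those whose groups did not overlap and did not pass, with adjusted p from 0.0818 to 0.285. Such separation was found for 13.7% of all entries, where chance gives 10%. Of these, 3 were higher in PINCH1 mutants. Fbxl15, which lies over Cuedc2, had a log2 fold change of 1.31 (SE 0.27), the keratin gene Krt10, which lies over Gm11940, one of 1.67 (SE 0.36), and the transcription factor gene Onecut2 one of 1.93 (SE 0.50). Those below controls were the ferritin heavy chain gene Fth1, 82 bp from Best1 (-0.99, SE 0.22), the pentose phosphate enzyme gene Taldo1, 4826 bp from Gatd1 (-2.16, SE 0.49), Stard13 (-2.18, SE 0.52) and Rnf10, within the span of Gm13831 (-1.67, SE 0.44). Also below were the metallothionein gene Mt2, over Gm45774 (-2.32, SE 0.56), and Ecscr, over 1700066B19Rik (-1.52, SE 0.39). Counts were few in the PINCH1 mutant libraries for Taldo1 and Stard13 (3 to 7 each) and Mt2 (4 to 9). Dnajc7, which lies over Nkiras2 and the myelin gene Cnp, was at -0.94 (SE 0.22).

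Of the 34 lists with a tested member, 4 were called in PINCH1 mutants. Of 20 tested genes for peripheral myelin proteins, 17 had a log2 fold change below 0 with a median of -0.27 (adjusted p = 0.00613, or adjusted p = 0.642 with an estimated correlation). No member passed over all entries, and 5 passed when adjusted over the list alone. Among them were Mbp (-0.61, SE 0.17), the periaxin gene Prx, over Gm15541 (-0.53, SE 0.18), Drp2 (-0.62, SE 0.21) and the gap junction gene Gjb1 (-2.20, SE 0.63). The change of Gjb1 rests on few counts, 3, 3 and 3 in the PINCH1 mutants against 7, 19 and 17 in controls. Mbp passed over all entries with the filter of at least 1 CPM in at least 3 libraries, but in no other setting, also not with no filter. Of 13 genes for fatty acid and myelin lipid synthesis, 12 were below 0 with a median of -0.40 (adjusted p = 0.00871, or adjusted p = 0.51 with an estimated correlation). The desaturase gene Fads1 (-0.97, SE 0.30) passed when adjusted over the list alone, and Scd2, with the highest count of this list, was at -0.32 (SE 0.17). Of 14 actin cytoskeleton genes and targets of serum response factor, 12 were below 0 with a median of -0.63 (adjusted p = 0.0159, or adjusted p = 0.51 with an estimated correlation), and 0 passed when adjusted over the list alone. Actb was at -0.62 (SE 0.26), and Tagln, which lies over Gm48529, at 0.03 (SE 0.25). The keratinocyte list was called as higher on its 1 tested entry, Krt10 (adjusted p = 0.0242, or adjusted p = 0.51 with an estimated correlation).

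The entries without a partner as a whole had a median log2 fold change of -0.19 in this comparison and those with a partner one of 0.05. Of the 1725 entries without a partner outside every list, 63.9% were below 0, a share to set beside the list counts. Of the called lists, 15 of the 20 myelin entries, 11 of the 13 lipid entries and 10 of the 14 actin entries were without a partner. With each class scaled separately, 0 lists were called, and the smallest adjusted p was 0.0732. The calls were also lost without control replicate 2, control replicate 3 or PINCH1 mutant replicate 2, while 8 lists were called without PINCH1 mutant replicate 1. The lipid call was lost without PINCH1 mutant replicate 3 as well. The level of entries without a partner differed between the groups by -0.18 on the log2 scale (two-sided exact permutation p = 0.2, where 0.1 is the smallest that 3 against 3 libraries allow).

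**Figure D2:**
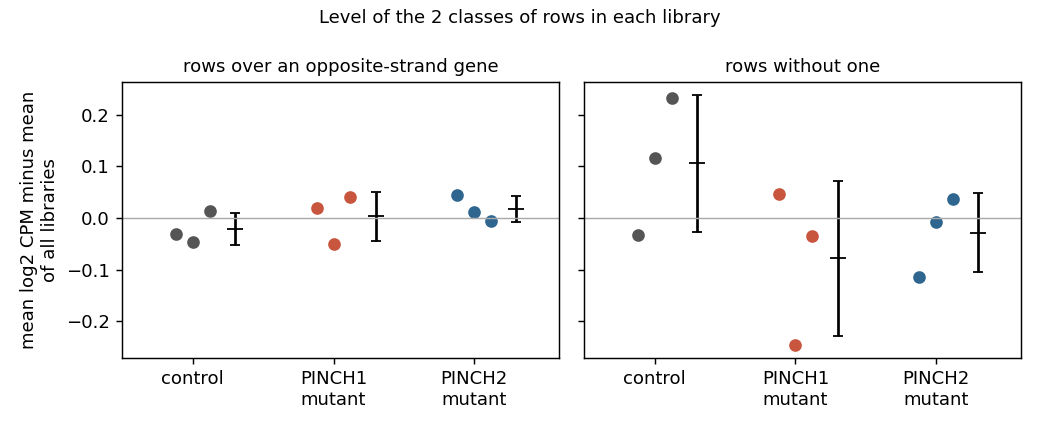
Mean log2 CPM of the tested entries that lie over an opposite-strand gene (left) and of those that do not (right), 1 point per library, as the difference from the mean of all 9 libraries, with the mean ± SD of each group of 3. Entries without a partner ran from -0.25 in PINCH1 mutant replicate 2 to 0.23 in control replicate 3, while entries with one stayed between -0.05 and 0.04.

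The other 30 lists had adjusted p from 0.0665 to 0.982 in PINCH1 mutants. Of 10 cell cycle genes, 9 were above 0 with a median of 0.29 (adjusted p = 0.0665), led in counts by Kif20a (0.44, SE 0.18), a mitotic kinesin gene over Cdc23, and Ccne2 (0.28, SE 0.21), a cyclin gene over Ints8. Of 42 genes for cytosolic ribosomal proteins, 33 were below 0 (median -0.25, adjusted p = 0.0665). Of 13 genes for the integrin-linked kinase complex and focal adhesions, 8 were below 0 (median -0.11, adjusted p = 0.876), and Ilk was at 0.11 (SE 0.18) and Itgb1 at 0.09 (SE 0.22). In 2 of the lists not called, 1 member passed when adjusted over the list alone: Scn7a of the nonmyelinating Schwann cell list (-1.88, SE 0.53) and Ndrg1, over Gm17035, of the glycolysis and hypoxia list (-0.59, SE 0.18). Markers of macrophages (adjusted p = 0.162), skeletal muscle (0.162), perineurial cells (0.41), adipocytes (0.41), neurons (0.631), erythroid cells (0.774), endothelial cells (0.804), fibroblasts (0.804), sex-linked genes (0.877) and pericytes (0.968) were not called. The adipocyte, erythroid, neuron and sex-linked lists each had 1 tested member, the endothelial list 2 and the pericyte list 3. The macrophage and muscle lists had 4 and the fibroblast and perineurial lists 5. These are too few to speak for the cell makeup of the nerve. The lists for mast cells, lymphocytes and neutrophils had 0 tested members. The remaining lists included myelination transcription factors, cholesterol synthesis, immature and repair Schwann cells, basal lamina, neuregulin and Notch signalling, YAP/TAZ targets, fibrillar collagen, immediate early genes, unfolded protein response, heat shock, interferon, complement and MHC class II, nuclear and mitochondrially encoded respiratory genes, with adjusted p from 0.188 to 0.982.

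The comparison of PINCH2 mutants with controls asks the same of PINCH2. Gpr17, the entry that lies over the targeted gene Lims2, was lower in the mutants, at 104 ± 32.3 CPM (SD, n = 3) against 290.4 ± 79.4 in controls, or 0.361 of the control level. It was the only entry that passed with edgeR, and 0 entries were higher. Entries named for lipid synthesis, actin and ribosomal protein genes lay below the other entries as lists, but 0 of their members passed singly over all entries. The list calls were lost with an estimated correlation.

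The log2 fold change of Gpr17 was -1.47 (SE 0.24, edgeR adjusted p = 0.0212). Of the 4738 entries, 79 were higher and 123 lower at an unadjusted p under 0.05, 202 in all, where 236.9 were due by chance. DESeq2 called 0 entries higher and 1 lower, and limma-voom called 0 in either direction. The Gpr17 call was also lost with the 6 libraries alone, with the replicate number as a block and at an adjusted p of 0.01. It was lost as well without control replicate 1, control replicate 3, PINCH2 mutant replicate 1 or PINCH2 mutant replicate 3. Each of these settings left 0 entries.

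The 10 entries next in order did not pass, with adjusted p from 0.934 to 0.999, and 9.05% of all entries had no overlap between the groups, where chance gives 10%. Those below controls were the polyamine enzyme gene Sat1 (-2.11, SE 0.50), the very long chain fatty acid elongase gene Elovl1, which lies over Cdc20 (-1.17, SE 0.31), the actin gene Actb (-1.01, SE 0.27), Rap2a (-1.90, SE 0.55) and Spag9, within the span of Gm11518 (-0.88, SE 0.26). Sat1 had 2 to 11 counts and Rap2a 3 to 9 in the PINCH2 mutant libraries. Those above were Srrt, 39 bp from Ufsp1 (1.64, SE 0.46), Krt10 (1.23, SE 0.36), Zfp652, over Abi3 and Zfp652os (0.82, SE 0.24), Epb4.1, over Gm10300 and Gm13063 (0.64, SE 0.19), and Camk4 (0.91, SE 0.28).

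In PINCH2 mutants 3 lists were called. Of 13 genes for fatty acid and myelin lipid synthesis, 11 were below 0 with a median of -0.40 (adjusted p = 0.00104, or adjusted p = 0.418 with an estimated correlation). Elovl1 passed when adjusted over the list alone, and Scd2 was at -0.26 (SE 0.17). Of 14 actin and serum response factor genes, 12 were below 0 with a median of -0.68 (adjusted p = 0.00172, or adjusted p = 0.418 with an estimated correlation), and Actb passed when adjusted over the list alone. Of 42 ribosomal protein genes, 31 were below 0 with a median of -0.19 (adjusted p = 0.0139, or adjusted p = 0.691 with an estimated correlation), and 0 passed when adjusted over the list alone. Rps25, over Trappc4, was at -0.03 (SE 0.22). Entries without a partner had a median of -0.13 and those with one 0.04. Of the 1725 entries without a partner outside every list, 59.7% were below 0. With the classes scaled separately, the lipid and actin lists had an adjusted p of 0.00563 and the ribosomal list one of 0.0903. Without control replicate 1 there were 5 called lists and without control replicate 3 there was 1. The ribosomal call was lost without any 1 of the controls and without PINCH2 mutant replicate 1, and the lipid call without control replicate 3.

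The other 31 lists had adjusted p from 0.0857 to 0.833 in PINCH2 mutants. Of 20 myelin protein genes, 14 were below 0 with a median of -0.23 (adjusted p = 0.115), and 0 passed when adjusted over the list alone. Pmp22 was at -0.26 (SE 0.13). The heat shock gene Hspa8 (-0.97, SE 0.29) passed when adjusted over its list alone, but the list was not called (adjusted p = 0.166). Of the markers of other cell types, the keratinocyte list had the smallest adjusted p (0.0857, Krt10 alone), followed by skeletal muscle (0.115) and endothelial cells (0.14).

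The direct comparison of the mutants asks whether they differ from each other. Zdhhc17 and Gpr17 were higher in PINCH1 than in PINCH2 mutants and Camk4 and RP24-538B17.1 were lower, 2 entries in each direction. Zdhhc17 stood at 397 ± 47.2 against 75.2 ± 5.24 CPM (SD, n = 3), Gpr17 at 311 ± 39.9 against 104 ± 32.3, Camk4 at 30.01 ± 5.65 against 179 ± 39.4 and RP24-538B17.1 at 10.5 ± 3.09 against 51.6 ± 14.9. No list was called as different.

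The log2 fold changes, as PINCH1 minus PINCH2 mutants, were 2.40 (SE 0.19, edgeR adjusted p = 9.56e-08) for Zdhhc17, 1.57 (SE 0.24, adjusted p = 0.00288) for Gpr17, -2.57 (SE 0.30, adjusted p = 6.97e-05) for Camk4 and -2.29 (SE 0.38, adjusted p = 0.00726) for RP24-538B17.1. At an unadjusted p under 0.05 there were 301 entries, where 236.9 were due by chance. RP24-538B17.1 lost its call with limma-voom and without PINCH1 mutant replicate 3 or PINCH2 mutant replicate 3, each of which left 1 lower entry. There were 5 higher entries with the 6 libraries alone and without PINCH1 mutant replicate 2, 5 higher and 4 lower without PINCH2 mutant replicate 2, and 4 in each direction without control replicate 2.

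The 10 entries next in order had adjusted p from 0.0533 to 0.218, and 521 of the 4738 entries had no overlap between these groups, where chance gives 10%. Above 0 were the entries named for the mitotic genes Kif20a, over Cdc23 (0.75, SE 0.18), and Ccna2, over Exosc9 (0.82, SE 0.21), with Dnahc11, over Cdca7l (1.10, SE 0.28), and Fbxl15 (0.99, SE 0.26). Cttnbp2nl, over Gm40117, stood at 100.6 ± 19.4 CPM against 201 ± 22.6. Also below 0 were the chloride channel gene Clcn1, over Fam131b (-1.73, SE 0.42), Gjb1 (-2.48, SE 0.62), Flad1, 2225 bp from Gm15417 (-1.50, SE 0.38), Zxdc, over Cfap100 (-0.94, SE 0.24), and Itfg2, over Nrip2 (-2.11, SE 0.56). In the PINCH1 mutant libraries Gjb1 had 3 counts each and Itfg2 had 4 to 9.

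All 34 lists had adjusted p from 0.711 to 0.998 between the mutants. Adjusted over the list alone, the Kif20a and Ccna2 entries, of the 10 for cell cycle genes, passed as higher in PINCH1 mutants (list median 0.17, adjusted p = 0.731). They lie over Cdc23 and Exosc9 and are not shown to measure Kif20a and Ccna2. The paxillin gene Pxn of the focal adhesion list also passed as higher (adjusted p = 0.968 for the list). Gjb1 of the myelin list (adjusted p = 0.731) and Cdh2 of the immature and repair Schwann cell list (adjusted p = 0.968) passed as lower.

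The changes of the 2 mutants against the same 3 controls were correlated across the 4738 entries, with a Pearson r of 0.466 and a covariance of 0.119. Genes are not independent replicates. Simulated unchanged groups, with their shared controls also drawn anew each time, gave a mean r of 0.499 and a mean covariance of 0.115. In 100 draws, covariances ran from 0.105 to 0.127 and r from 0.457 to 0.535. The observed values lay within both ranges. Entries were drawn independently, so the ranges leave out shifts that many entries of a library share. No entry passed in the same direction in both comparisons, where independent lists would share 0 higher and 0.000422 lower entries. The 3 controls were too few to give each mutant 2 of its own, so they were not split.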

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

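The tests of Csrp2 and of chromosome 10 were chosen after the results were seen. The effect of each mutation against control differed between the mutants for 4 entries, by a direct edgeR test of the PINCH1 minus PINCH2 difference: Zdhhc17 (log2 difference 2.40), Gpr17 (1.57), Camk4 (-2.57) and RP24-538B17.1 (-2.29). All 3 libraries of one mutant lay above all 3 of the other for each of them.

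Zdhhc17 was higher in 3 of 3 PINCH1 mutant libraries, and its call was kept in all 19 other settings of either comparison. As a technical explanation, reads that run past the annotated end of Csrp2, 2160 bp away on the other strand, may be counted under Zdhhc17. The Csrp2 entry itself had 8, 2 and 4 counts in controls and 19, 9 and 8 in PINCH1 mutants. Its log2 fold change was 1.31 with an SE of 0.84, which leaves this explanation open. The counts are few, and the explanation needs reads to be counted on the opposite strand. In that case the Csrp2 entry would not hold most reads of Csrp2, so it could not decide at any depth. Another explanation is DNA carried along with the mutated Lims1 allele: of the 60 tested entries within 20 Mb of Lims1, 1 had an unadjusted p under 0.01 (1.67%), against 1.67% of the others (Fisher's exact p = 1, two-sided), and on all of chromosome 10 it was 4 of 218 (Fisher's exact p = 0.784). The bound set beforehand, a share near Lims1 no higher than elsewhere, was met, but the 95% binomial limit of that share reached 8.94%, a criterion of spread added after the result was seen. With so few such entries, and Zdhhc17 52.6 Mb from Lims1, this cannot be told apart from an effect of the mutation on Zdhhc17 or Csrp2, which stays open and untested.

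With 3 libraries against 3 there are 10 splits of the 6, too few for a share under 0.05. PINCH1 mutants against controls gave 3 called entries and the highest of the other splits gave 3, so that 2 of the 10 splits gave as many. For PINCH2 mutants against controls the values were 1 and 2, with 3 of the 10 splits giving as many. For the comparison between the mutants they were 4 and 3, and 1 split, the real one, gave as many.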

How the results depend on the processing

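Separate scaling of entries with and without a partner (class scaling), a minimum of 3 members per list and the use of opposite-strand entries were chosen after the data were seen. RLE, upper-quartile scaling, TMM without the 20 most abundant entries, DESeq2 and a 1.5-fold minimum left each count of calls within 1.5 times. For PINCH1 mutants against controls, higher and lower entries numbered 8 and 7 with no filter, 8 and 8 with at least 1 CPM in at least 3 libraries, 1 and 0 with limma-voom, with the 6 libraries alone and at an adjusted p of 0.01, and 1 and 1 with class scaling. For PINCH2 mutants, 0 lower entries were left with limma-voom, the 6 libraries alone and an adjusted p of 0.01. Between the mutants the numbers were 12 and 8 with no filter, 13 and 14 with at least 1 CPM, 5 higher with the 6 libraries alone and 1 lower with limma-voom. Looser filters test more entries of few counts. Yet Fbxl15, Krt10, Fth1, Dnajc7, Mt2 and Onecut2, called with both looser filters in PINCH1 mutants, were also tested under the main filter. The cause of these and the other differences was not tested. With 1 library left out the ranges were 1 to 4 higher and 0 to 5 lower, 0 to 1 lower, and 2 to 5 higher and 1 to 4 lower in the 3 comparisons. Called lists ranged from 0 to 8 in PINCH1 and from 1 to 5 in PINCH2 mutants. Both fell to 0 with an estimated correlation, with fry and through opposite-strand entries, where 1 list was called between the mutants, and PINCH1 lists fell to 0 with class scaling. Through opposite-strand entries, of which the actin list had 1, the lipid list 2 and the ribosomal list 4, the lipid (adjusted p = 0.947) and actin (0.621) lists in PINCH1 mutants and the actin (0.634) and ribosomal (0.988) lists in PINCH2 mutants turned to higher without a call, on too few entries to speak for the lists. The correlation of the mutants' changes ranged from 0.356 to 0.587. The named entries kept their direction in every setting that tested them, and their side of the threshold in 670 cases, with 26 calls gained and 25 lost. Fitted without the filter, Lims1 in PINCH1 mutants and Lims2 in PINCH2 mutants against controls stayed below 0 and did not pass with RLE, DESeq2, the 6 libraries alone or any 1 library left out, at 4 to 17 counts per group. Whether depth or the strand counted keeps these counts low was not tested.

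The replicate numbers were not taken as pairs. Over all tested entries, the deviations of same-numbered libraries correlated at -0.11 to 0.25, with only 3 of 9 pairs over 0.1. Those of different-numbered libraries correlated at -0.20 to 0.14, so a batch shared by number is not excluded. As a hint from the data of something shared by number, 5 of 9 libraries correlated best with their own number. In CPM, mt-Co2, mt-Co3, mt-Atp6, mt-Atp8, mt-Nd3 and mt-Nd4l were lowest in replicate 2 of each group. These mitochondrial entries thus shared a pattern by number, for which the main model has no term. Of them, mt-Co2 and mt-Co3 were also highest in replicate 3 of each group, while mt-Atp6 was highest in replicate 1 of the PINCH2 mutants. In the PINCH2 mutants mt-Co1 and mt-Cytb were lowest in replicate 1. With the replicate number as a block, there were 2 higher and 3 lower entries in PINCH1 mutants, 0 in PINCH2 mutants, and 3 and 3 between the mutants, with Afap1l1 among the lower ones in the first and last, and with 3 lists called in each mutant, the keratinocyte list no longer among them.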

Other observations

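The tests of strand, of the ratio between paired entries and of single chromosomes, and the reading of lists through opposite-strand entries, were chosen after the results were seen. When list members were read through the entries that lie over them, 0 lists were called in either mutant against controls and 1 between the mutants. The cell cycle list was higher in PINCH1 than in PINCH2 mutants on 4 entries with a median log2 difference of 1.02 (camera adjusted p = 0.00531, or adjusted p = 0.883 with an estimated correlation). In PINCH1 mutants against controls, Exosc9, over Ccna2, was at 1.11 (SE 0.61), Cdc23, over Kif20a, at 0.98 (SE 0.50), Ints8, over Ccne2, at 0.28 (SE 0.52) and Elovl1, over Cdc20, at -0.53 (SE 0.30). In PINCH2 mutants they were at -0.57 (SE 0.64), -0.42 (SE 0.52), -0.08 (SE 0.53) and -1.17 (SE 0.31), in the same order. Among entries over the integrin adhesion genes, Taf10, over Ilk, was at 0.01 (SE 0.14) in PINCH1 and -0.02 (SE 0.14) in PINCH2 mutants, and Ap3m1, over the vinculin gene Vcl, at 0.11 (SE 0.15) and -0.18 (SE 0.15).

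Chromosome 18, which carries Lims2, held more entries with an unadjusted p under 0.01 than other chromosomes. In PINCH1 mutants against controls they were 7 of 95 tested entries (7.37%, against 1.55% elsewhere; Fisher's exact p = 0.000932, adjusted p = 0.0186 over 20 chromosomes). Between the mutants they were also 7 of 95 (adjusted p = 0.016). In PINCH2 mutants against controls they were 3 (adjusted p = 0.742). Within 20 Mb of Lims2, 5 of 56 entries had such a p between the mutants (8.93%, against 1.54% of the others; Fisher's exact p = 0.00199), and 4 of 55 without Gpr17 (p = 0.0112). In PINCH2 mutants against controls, 2 of the 56 entries within 20 Mb of Lims2 had such a p. This was 3.57%, against 0.75% of the others (Fisher's exact p = 0.0702). Entries of chromosome 18 with such a p between the mutants were Gpr17, Camk4, 1.01 Mb from Lims2, Kif20a, Fgf1, Cdh2, Onecut2 and Afap1l1. Onecut2 and Afap1l1 lie outside the 20 Mb. Against controls, Fgf1, Cdh2, Onecut2 and Afap1l1 had such a p in PINCH1 mutants (edgeR unadjusted p from 0.000857 to 0.00818). In PINCH2 mutants theirs ran from 0.239 to 0.849. Camk4 had such a p in both mutants, in opposite directions, Gpr17 in PINCH2 mutants only, and Kif20a in neither. The share within 20 Mb of Lims2 was not tested for PINCH1 mutants against controls. Afap1l1, over 1500015A07Rik, had 40, 5 and 59 counts in controls, 0, 0 and 1 in PINCH1 mutants and 78, 21 and 107 in PINCH2 mutants (edgeR adjusted p = 0.492 for PINCH1 mutants against controls and 0.281 between the mutants). Between the mutants it passed with DESeq2, with no filter (adjusted p = 0.0467), with the 6 libraries alone and without control replicate 2 or PINCH2 mutant replicate 2, and against controls it passed in PINCH1 mutants without control replicate 2. Several mitochondrial entries varied between the libraries of every group: mt-Co2 had 274, 4 and 1373 counts in controls, 197, 32 and 1106 in PINCH1 mutants and 544, 9 and 805 in PINCH2 mutants.

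Most counts lay on entries overlapped by a gene of the opposite strand. A candidate explanation is that reads were counted on the strand opposite to each gene. In every library, mt-Nd6 took at least 80.9% of the mitochondrial counts. Of the 100 entries with the most counts, 93 had a partner, against 24.7% of all entries. These values argue against counting on each gene's own strand, for the mitochondrial entries and the highest entries as sets. Counting without regard to strand is argued against, since the partner's entry had a median of 0.0152 of the counts of the entry among the 100 highest pairs. Whether the Gpr17 entry holds reads of Lims2 was not tested, and whether other single entries hold their own or their partner's reads stays open.

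Entries without a partner had a median log2 fold change of -0.19 in PINCH1 mutants, but the level per library overlapped that of controls (exact permutation p = 0.2). A difference between libraries in the share of reads on the minority strand may contribute: over the 9 libraries, the median ratio of the partner's entry to the entry correlated with the level of entries without a partner (r = 0.702, permutation p = 0.0321). This was over 99 of the 100 highest pairs, after 1 pair whose partner's entry had no partner itself was dropped (r = 0.753 with it). The log2 ratio differed between PINCH1 mutants and controls by -0.10 (exact permutation p = 0.5), so a difference between the groups was not shown. Lower expression of myelin genes stays open. The 4 entries that lie over myelin genes had a median of 0.14, above the bound of 0 set to argue against it, but they went both ways. That bound was set before this test was run but after the pattern was seen. Dnajc7, over Nkiras2 and Cnp, was at -0.94 (SE 0.22), Gm15541, over Prx, at 0.31 (SE 0.58), Gm12927, over Cldn19, at 0.17 (SE 0.15) and Gm16350, over Arhgef10, at 0.10 (SE 0.29), and the criterion of spread was added after the result was seen.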
